A study of Mus musculus with 12 samples.

How the data were processed

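The unit was given as signal, and the deposited table held 23988 genes in 12 libraries, 3 for each of 4 groups: WT, AKO (floxed Rab11a with the tamoxifen-inducible villin Cre), BKO (Rab11b null) and DKO (both). No column belonged to a sample outside the series, and 0 gene names were duplicated. Per the submitters' processing notes, reads were checked with FastQC 0.11.3 and trimmed with Trimmomatic 0.36, DESeq2 was used without a stated version, and the build was mm9. The name of the table mentions HISAT2, an aligner, and both FPKM and fpm, without a version or a role. The counting tool, the gene annotation and any filter are not given in the sources used here. The library kit does not mark the strand.

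In each library 100% of the values were whole multiples of 1 step, within 0.001 reads, and that step was the same for all genes, which excludes division by gene length. The steps, taken as the value of 1 read, were 0.0313 to 0.0563, and the reads recovered with them were 19.2 M to 29.8 M per library. Column sums were 0.908 M to 1.08 M, so the values are read as fragment counts scaled by size factors (fpm). The unit of the deposited values therefore allowed count tests. The planned test had assumed normalized values, so limma on the deposited values was kept for the reported calls and the count tests were run beside it on recovered reads. DESeq2 called 3 genes in AKO against WT, 249 in BKO against WT, 5165 in DKO against WT, 5139 in DKO against AKO, 4097 in DKO against BKO and 1783 in the interaction. The edgeR quasi-likelihood test called 1, 5, 4145, 4283, 3025 and 352 in the same order.

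The reported test was limma with a trended prior on log2 of the value plus 1, with 1 coefficient per group and all 12 libraries, for the 13675 genes with a value of at least 1 in at least 3 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided test. Each gene had 1 spread for all 4 groups, so a wide spread within 1 group was averaged over all of them. The interaction was DKO minus AKO minus BKO plus WT, the part of the DKO change that the sum of both single changes did not hold on the log scale. Errors of log2 changes are standard errors from the fit, and errors of means are standard deviations of 3 libraries. The groups, the tests, the gene lists, the rule for named genes and the alternatives were set before the data were examined.

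Lists of marker genes were written from general knowledge for 40 groups: the Rab11 family with its partners, spindle and mitosis, other G2 and M phase genes, S phase, p53 targets, intestinal stem cells, fetal-like or YAP-driven genes, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, fat uptake, brush border, villus tip, antimicrobial genes, junctions, type I interferon, interferon gamma, MHC class II, inflammatory genes, unfolded protein response, cholesterol synthesis, xenobiotic metabolism, circadian genes, heat shock with immediate early genes, proximal and distal intestine, mitochondrially encoded genes, smooth muscle, neurons and glia, fibroblasts, endothelium, B and plasma cells, T and NK cells, macrophages and dendritic cells, neutrophils with eosinophils and mast cells, red blood cells, adipose tissue and pancreas. The 36 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. With an estimated correlation 0 of the 36 lists were called in any comparison, with all libraries or without any 1 of them, except 2 in AKO against WT without AKO replicate 2. Counts of called members are given over all genes and adjusted over the list alone.

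The named genes were Rab11a, Rab11b and Rab25 in every comparison. In each comparison with WT they were also the 10 largest log2 changes in each direction among called genes without overlap between 3 and 3 libraries and with a mean of at least 2 in the higher group. In DKO against AKO, DKO against BKO and the interaction they were the 5 largest in each direction, the interaction without the overlap rule. For each list with a camera adjusted p under 0.05 up to 4 members with the smallest p were named, for other lists with a called member in DKO against WT up to 2, and for lists of other cell types up to 2 with the highest mean. Symbols of predicted or unnamed genes were passed over. The text gives values for a part of these genes. A comparison without a call would have given the 5 smallest raw p.

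Alternatives set in advance were a pseudocount of 0.1 or 5, no filter (18200 genes), a filter of at least 5 in 3 libraries (11134 genes), median-of-ratios scaling, quantile scaling, only the groups compared, quality weights, a replicate block, edgeR (14824 genes) with and without its filter, DESeq2 (18200 genes), and each of the 12 libraries left out in turn. The median-of-ratios factors were 1.004 to 1.005, so that setting changed almost nothing and tests no scaling. Alternatives chosen after seeing the data were scaling by the total reads of each library, the state of Xist as a term, BKO replicate 3 and WT replicate 2 both left out, older gene symbols matched to list members, and an estimated correlation with each library left out in turn. For the excess of called genes near Rab11b, gene positions in GRCm38 were used only to find the genes within 10 megabases, since the files name another build, and no coordinates are given.

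A self-test with simulated counts placed 100 genes changed 2-fold and 100 changed 4-fold among 13531 tested genes. Its spread was taken from the WT and AKO libraries, and no outlying library was simulated. For DKO against WT limma found 57 and 95 of them with 7 unchanged genes called, and for the interaction 22 and 79 with 5 unchanged genes called. For comparisons simulated without any change limma and edgeR called 0 genes, and DESeq2 called 9 and 13. A list shifted by 0.5 log2 was found, with no other of the 36 lists. Genes were simulated independently of each other, so this cannot show how often camera calls unchanged lists of correlated genes. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.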

Results

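RNA of whole jejunum from adult mice was compared between 4 groups of 3 libraries: WT, AKO, in which floxed Rab11a is removed from the intestinal epithelium by an inducible villin Cre, BKO, with the Rab11b null genotype, and DKO, with both. All mice had received tamoxifen at 40 mg/kg, and tissue was taken 2 days later. Rab11a and Rab11b encode closely related small GTPases of recycling endosomes, and the title of the series names a redundant role of both in the mitotic spindle of dividing progenitor cells. The labels do not say whether WT and BKO mice carried the floxed allele or Cre, so an effect of Cre with tamoxifen was not separated from the loss of Rab11a. The comparisons ask what each loss changes alone and what appears only when both are missing. The labels do not say that the numbered samples are separate animals, so each p-value measures the spread between these samples. By chance alone, 3 values against 3 show no overlap in 10% of cases.

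Rab11a fell in AKO from 186 ± 3.87 to 59.4 ± 9.43 (log2 change -1.64 ± 0.15, adjusted p = 0.00361, n = 3 per group) and in DKO to 106 ± 8.48 (-0.81 ± 0.15, adjusted p = 0.00284). It was higher in DKO than in AKO by 0.83 ± 0.15 (adjusted p = 0.00254), and its interaction of 0.54 ± 0.21 was not called (adjusted p = 0.145). In BKO, Rab11a was at 230.0 ± 39.7 (adjusted p = 0.495). Whole jejunum also holds cells outside the epithelium, in which the villin Cre is not active. Rab11b fell from 116 ± 5.07 in WT to 27.0 ± 4.23 in BKO (-2.07 ± 0.12, adjusted p = 2.58e-05) and 22.9 ± 1.55 in DKO (-2.30 ± 0.12, adjusted p = 1.06e-05), and AKO was at 112 ± 6.67 (adjusted p = 1). Rab25, the epithelial relative of both, was at 84.0 ± 6.19 in WT, 83.5 ± 3.55 in AKO, 90.3 ± 19.1 in BKO and 98.3 ± 7.08 in DKO, and was not called in AKO, BKO or DKO against WT (adjusted p = 1, 0.867 and 0.241).

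**Figure D1:**
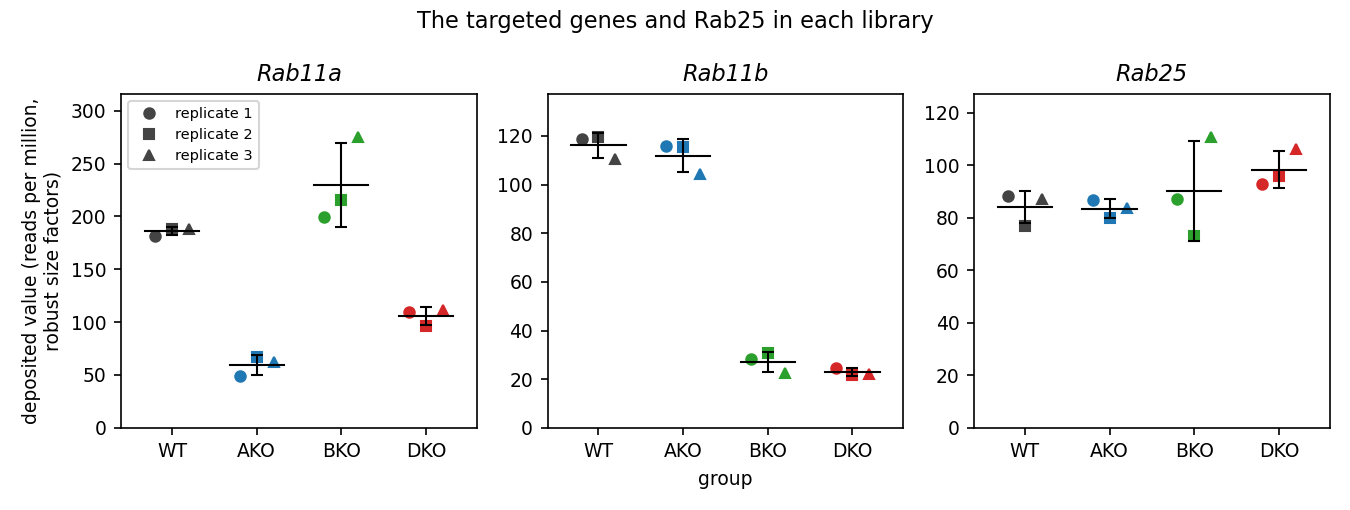
Rab11a, Rab11b and Rab25 in each library (points, replicates 1 to 3), with the mean and standard deviation of each group of 3; values as deposited, axis from 0.

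On the first principal component, which held 58.5% of the variance, the DKO libraries lay at 64.1 to 71.6 and BKO replicate 3 lay near them at 52.8, while all other libraries lay at -36.7 to -27.2. On the second component (12.9%) BKO replicate 3 stood apart at -63.4. Against the mean of the other BKO libraries, BKO replicate 3 lay in the direction of the DKO change for 82% of the genes called in DKO against WT. It carried high fetal-like genes (Anxa1 at 149.5, Il1rn at 183) and few transcripts of T cells and antigen presentation (Cd3e at 0, Ciita at 0.367), with Rab11a at 275. WT replicate 2 held the most B-cell transcripts (Cd79a at 141), and its B and plasma cell list lay 2.08 log2 above the WT mean.

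**Figure D2:**
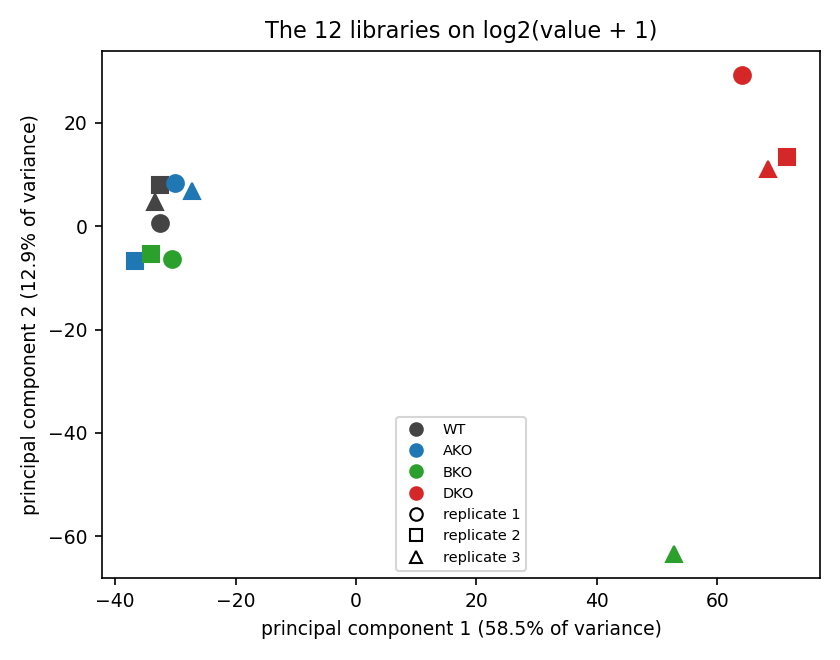
First and second principal component of the 12 libraries, with the share of the variance on each axis. Points are coloured by group, with a marker shape for each replicate.

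In AKO against WT, Rab11a was the only gene called of 13675 by limma (0 higher, 1 lower), and edgeR called 1 and DESeq2 3. Only 136 genes had an unadjusted p under 0.05, a smaller share than 0.05 of all genes, so the test was conservative here. That number was 318 without BKO replicate 3, 382 with only these groups in the fit and 1462 with quality weights. The few calls therefore do not show that AKO changed little. As groups, p53 targets, fibroblast and endothelial genes lay higher and cholesterol synthesis lower, each by a small amount and with 0 called members. The p53 targets had a median of 0.146 (camera adjusted p = 1.87e-05, adjusted p = 0.114 with an estimated correlation). Phlda3 was at 2.37 ± 0.379 in WT and 3.91 ± 0.713 in AKO and Plk2 at 4.81 ± 0.643 and 10.8 ± 5.79, neither called (adjusted p = 1 for both). Cholesterol synthesis had a median of -0.153 (camera adjusted p = 4.28e-09, adjusted p = 0.154 with an estimated correlation), with Mvd at 69.0 ± 3.91 in WT and 53.7 ± 3.65 in AKO, not called (adjusted p = 1). Fibroblast genes had a median of 0.423 (camera adjusted p = 1.87e-05, adjusted p = 0.258 with an estimated correlation) and endothelial genes 0.264 (5.94e-05, adjusted p = 0.447 with an estimated correlation). These 4 lists kept their camera call whichever library was left out, though without AKO replicate 2 the median was 0.032 for p53 targets and -0.24 for cholesterol synthesis. Without that library cholesterol synthesis (adjusted p = 0.0496) and fat uptake (adjusted p = 0.0434) were called with an estimated correlation too.

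Of the other lists, camera called 8 more in AKO against WT that did not survive every left-out library, and fry called 0 of 36. Enteroendocrine genes (median 0.117, adjusted p = 0.0149, adjusted p = 0.503 with an estimated correlation) lost the call without WT replicate 2 (0.207), AKO replicate 1 (0.109) or AKO replicate 2 (0.245). Fat uptake genes (-0.20, adjusted p = 0.0088, adjusted p = 0.561 with an estimated correlation) lost it without WT replicate 1 (0.0941), AKO replicate 1 (0.187) or AKO replicate 3 (0.312). Villus tip genes (-0.165, adjusted p = 0.022, adjusted p = 0.447 with an estimated correlation) lost it without WT replicate 1 (0.188) or AKO replicate 1 (0.119). Inflammatory genes (-0.264, adjusted p = 0.0453, adjusted p = 0.978 with an estimated correlation) lost it without WT replicate 2 (0.479), AKO replicate 1 (0.251) or AKO replicate 2 (0.179). The unfolded protein response (-0.141, adjusted p = 0.0453, adjusted p = 0.978 with an estimated correlation) lost it without WT replicate 1 (0.677), AKO replicate 1 (0.454) or DKO replicate 2 (0.0532). Smooth muscle genes (0.244, adjusted p = 0.0416, adjusted p = 0.978 with an estimated correlation) lost it without WT replicate 2 (0.954) and turned to -0.040 without AKO replicate 2 (0.718). B and plasma cell genes (-0.97, adjusted p = 0.000412, adjusted p = 0.447 with an estimated correlation) lost it without AKO replicate 2 (0.267). T and NK cell genes (-0.555, adjusted p = 0.0142, adjusted p = 0.978 with an estimated correlation) lost it without WT replicate 2 (0.136) or AKO replicate 2 (0.225). Where these calls held, some medians still moved by over 1.5 times: enteroendocrine genes to 0.189 (without WT replicate 1), 0.214 (WT replicate 3) and 0.313 (AKO replicate 3), fat uptake to -0.41 (AKO replicate 2) and villus tip to -0.28 (WT replicate 3). Smooth muscle moved to 0.382 (WT replicate 3) and 0.429 (AKO replicate 1), and B and plasma cells to -1.81, -0.43 and -1.84 (WT replicates 1, 2 and 3) and -1.46 (AKO replicate 1). The spindle list (median 0.030, adjusted p = 0.383), other G2 and M phase genes (0.020, adjusted p = 0.782), and S phase genes (-0.072, adjusted p = 0.456) were not called. Nor were enterocyte genes (-0.030, adjusted p = 0.967) and fetal-like genes (0.031, adjusted p = 0.672). The enterocyte median turned to 0.02 with quantile scaling and to 0.011 with scaling by total reads.

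In BKO against WT, 6 genes were called (1 higher, 5 lower; 1466 at an unadjusted p under 0.05), and edgeR called 5 and DESeq2 249. Beside Rab11b, the class I histocompatibility gene H2-Bl fell from 119.9 ± 11 to 4.96 ± 3.69 (log2 change -4.62 ± 0.47, adjusted p = 0.00491, n = 3 per group). Gdpd3, a phospholipase, fell from 39.9 ± 4.03 to 2.36 ± 2.6 (-3.87 ± 0.47, adjusted p = 0.0186) and Pianp from 4.44 ± 0.271 to 0.819 ± 0.149 (-1.58 ± 0.20, adjusted p = 0.0186). The potassium channel gene Kcnk6 rose from 28.8 ± 1.28 to 49.6 ± 1.94 (0.76 ± 0.11, adjusted p = 0.0492). The remaining call, Gm8801, chosen after its values were seen, was at 5.17 in WT, 5.02 in AKO and 0 in BKO and DKO (adjusted p = 2.58e-05). Scaled by the total reads of each library, 0 genes were called higher and 6 lower. In DKO against WT, H2-Bl (0.796 ± 0.201 in DKO; -6.07, adjusted p = 6.36e-05) and Gdpd3 (-3.02, adjusted p = 0.00157) also fell, Kcnk6 also rose (1.04, adjusted p = 0.000245), and Pianp was at 5.66 ± 1.57 (adjusted p = 0.323). Rab11b and H2-Bl kept their call whichever library was left out. With only the groups compared in the fit H2-Bl, Gdpd3, Pianp and Kcnk6 were not called, and with the replicate number as a block Gdpd3, Pianp and Kcnk6 were not. Gdpd3 was also not called by edgeR, Pianp with a pseudocount of 5 or quantile scaling, and Kcnk6 with a pseudocount of 5, the stricter filter, scaling by total reads, the Xist state as a term or edgeR without a filter. With BKO replicate 3 and WT replicate 2 both left out neither Pianp nor Kcnk6 was called. Gdpd3 lost it without WT replicate 1, WT replicate 2, WT replicate 3, BKO replicate 1, BKO replicate 2 or DKO replicate 2 (adjusted p up to 0.147). Pianp lost it without WT replicate 1, WT replicate 2, WT replicate 3, AKO replicate 3, BKO replicate 2 or DKO replicate 2 (up to 0.147). Kcnk6 lost it when any 1 library was left out except DKO replicate 3 (up to 0.391). The count was 3 without WT replicate 1, WT replicate 2, WT replicate 3 or DKO replicate 2, and 9 without BKO replicate 1. Without BKO replicate 3 it was 8, with Lancl3 (1.89, adjusted p = 0.0258), Pgap1 (0.74, adjusted p = 0.0258) and S100a11 (0.92, adjusted p = 0.0326) higher, all chosen after their values were seen.

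By list, BKO against WT showed lower antigen presentation and B-cell genes and higher fetal-like and cholesterol synthesis genes, and BKO replicate 3 lay farther out than the other BKO libraries in most of them. Camera called 17 lists (7 higher, 10 lower), fry 0 of 36, and the lowest adjusted p was 0.339 with an estimated correlation. The 8 lists kept whichever library was left out were fetal-like genes (median 0.914, adjusted p = 0.000223, adjusted p = 0.599 with an estimated correlation), then, with the same 3 values in this order, junctions (0.163, 0.000141; 0.599), interferon gamma (-1.09, 5.54e-07; 0.599), MHC class II (-2.25, 3.35e-06; 0.599), cholesterol synthesis (0.299, 5.64e-07; 0.339), heat shock with immediate early genes (0.543, 0.00385; 0.599), B and plasma cells (-2.61, 5.54e-07; 0.339) and macrophages (-0.597, 0.000574; 0.599). Several of these medians rested on BKO replicate 3. Without it they were 0.426 for fetal-like genes, -0.25 for interferon gamma, -0.40 for MHC class II and 0.227 for heat shock genes. Heat shock genes were at 0.342 without WT replicate 1, and macrophage genes at -0.92 without BKO replicate 1 and -0.36 without BKO replicate 2. No member was called over all genes, while adjusted over the list alone 3 fetal-like genes were higher, and 1 MHC class II, 6 B and plasma cell and 2 macrophage genes were lower. Ciita, the activator of MHC class II, chosen here after its values were seen, was at 92.0 ± 11.2 in WT and 44.0 ± 38.7 in BKO (adjusted p = 0.49). Mzb1 was at 31.3 ± 5.57 and 5.75 ± 5.8 (adjusted p = 0.333). S100a6 was at 179.7 ± 1.65 and 1058 ± 1073 (adjusted p = 0.337), with 2293 in BKO replicate 3.

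A further 9 lists in BKO against WT rested on single libraries. Smooth muscle (-0.685, adjusted p = 0.000774, adjusted p = 0.688 with an estimated correlation) and T and NK cells (-1.39, adjusted p = 9.59e-05, adjusted p = 0.599 with an estimated correlation) lost their call without BKO replicate 3 (0.451 and 0.21). Endothelium (-0.385, adjusted p = 0.00385, adjusted p = 0.599 with an estimated correlation) lost it without BKO replicate 2 (0.123). Paneth genes (0.395, adjusted p = 0.0322, adjusted p = 0.733 with an estimated correlation) lost it without WT replicate 1 (0.222), BKO replicate 1 (0.225), BKO replicate 3 (0.497) or DKO replicate 3 (0.0532). Antimicrobial genes (-0.832, adjusted p = 0.0247, adjusted p = 0.599 with an estimated correlation) lost it without WT replicate 1 (0.0619), WT replicate 3 (0.058) or BKO replicate 3 (0.567). Inflammatory genes (-0.372, adjusted p = 0.0496, adjusted p = 0.733 with an estimated correlation) lost it without WT replicate 2 (0.244), AKO replicate 1 (0.0537), AKO replicate 2 (0.0582), BKO replicate 1 (0.0578) or BKO replicate 3 (0.257). Tuft cell genes (0.393, adjusted p = 0.0438, adjusted p = 0.733 with an estimated correlation) lost it without WT replicate 3 (0.136) and turned to -0.068 without BKO replicate 2, with 0.658 without BKO replicate 3. The median of Paneth genes was 0.596 without WT replicate 2 and 0.905 without BKO replicate 2, and that of smooth muscle -1.13 without BKO replicate 2. Type I interferon genes (-0.463, adjusted p = 0.00894, adjusted p = 0.762 with an estimated correlation) lost it without WT replicate 1 (0.0631) or WT replicate 2 (0.108) and turned to 0.11 without BKO replicate 3. The unfolded protein response (0.112, adjusted p = 0.0268, adjusted p = 0.733 with an estimated correlation) lost it without WT replicate 2 (0.108) or WT replicate 3 (0.058) and turned to -0.051 without BKO replicate 3, with 0.187 without WT replicate 1, 0.205 without BKO replicate 1 and 0.24 without BKO replicate 2.

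Cell-cycle lists were not called in BKO against WT: spindle -0.019 (adjusted p = 0.82), other G2 and M phase 0.062 (adjusted p = 0.446) and S phase -0.089 (adjusted p = 0.4). The spindle list of BKO replicate 3 lay 0.693 above WT, and those of BKO replicates 1 and 2 lay at -0.20 and -0.54. Without BKO replicate 3 all 3 lists were called lower, spindle at -0.39 (adjusted p = 3.42e-10), other G2 and M phase at -0.28 (adjusted p = 0.00038) and S phase at -0.50 (adjusted p = 3.14e-13). These calls were lost with an estimated correlation (adjusted p = 0.525, 0.644 and 0.461). Without BKO replicate 2 spindle was called higher at 0.219 (adjusted p = 0.00435), which was lost with an estimated correlation (adjusted p = 0.831).

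DKO against WT changed 4348 genes (1995 higher, 2353 lower; 5996 at an unadjusted p under 0.05), 1888 of them at least 2-fold (958 higher, 930 lower); edgeR called 4145 and DESeq2 5165. Genes of digestion and uptake fell, genes of wounded or fetal-like epithelium rose, and spindle genes were not called as a group. These list calls come from camera at a preset correlation, and 0 of 36 lists were called with an estimated one (lowest adjusted p = 0.286). Among the largest rises, the interleukin 1 receptor antagonist Il1rn went from 5.17 ± 3.76 to 721 ± 76.8 (log2 change 7.03 ± 0.95, adjusted p = 0.000827, n = 3 per group). The growth factor gene Areg went from 6.83 ± 1.43 to 333 ± 73.1 (5.41 ± 0.51, adjusted p = 0.000164), and Retnlb from 0.275 ± 0.338 to 26.8 ± 7.05 (4.45 ± 0.30, adjusted p = 5.59e-05). Among the largest falls, the amine oxidase Aoc1 went from 1155 ± 130.5 to 20.9 ± 4.76 (-5.74, adjusted p = 0.00118), Arg2 from 84.2 ± 9.99 to 0.549 ± 0.222 (-5.79, adjusted p = 0.0009) and Cyp2c55 from 118 ± 29.5 to 0.257 ± 0.156 (-6.54 ± 1.00, adjusted p = 0.00139). Apol10a went from 539 ± 106 to 1.82 ± 0.922 (-7.62, adjusted p = 0.00363). Of the called genes, 4332 (99.6%) had no overlap between 3 and 3 libraries, as the test requires of most calls, and 34.2% of the uncalled genes had none either, against 10% by chance. Scaled by the total reads of each library, 2318 genes were higher and 1901 lower (54.9% higher, against 45.9%). Xist, a transcript of female animals, was high in all DKO libraries but in WT only in replicate 1. With the Xist state as a term 5283 genes were called. The count was 2742 without WT replicate 1, 2843 without WT replicate 3 and 2691 without DKO replicate 2, and DESeq2 did not call Il1rn.

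The enterocyte list fell furthest of the epithelial lists in DKO: its median was -1.88, with 18 of 20 members lower (19 adjusted over the list alone, camera adjusted p = 4.46e-09, adjusted p = 0.54 with an estimated correlation). Sis, encoding sucrase-isomaltase, went from 1912 ± 193 to 301 ± 68.2 (-2.68 ± 0.28, adjusted p = 0.000244) and the peptidase gene Enpep from 2920 ± 406 to 309 ± 25.9 (-3.23 ± 0.41, adjusted p = 0.000656). Fat uptake genes had a median of -0.934, 12 lower and 2 higher (the same adjusted over the list alone, adjusted p = 0.00429, adjusted p = 0.54 with an estimated correlation). The lipid-sensing receptor Ppara fell from 63.0 ± 4.85 to 6.51 ± 0.757 (-3.09 ± 0.39, adjusted p = 0.000606) and the cholesterol transporter Npc1l1 from 645 to 111 (-2.55, adjusted p = 0.00098). Brush border genes had a median of -0.822, 11 lower and 2 higher (12 and 2 adjusted over the list alone, adjusted p = 0.00703, adjusted p = 0.657 with an estimated correlation). Pdzk1 fell from 265 to 6.08 (-5.25 ± 0.84, adjusted p = 0.0017), and Baiap2l1 rose from 134 to 213 (0.65, adjusted p = 0.00816). That list lost its call without DKO replicate 3 (0.0612). Distal intestine genes had a median of -1.58, 6 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.0077, adjusted p = 0.557 with an estimated correlation). The bile acid genes Fabp6, at 8483 ± 2457 and 924 ± 186 (-3.17 ± 0.51, adjusted p = 0.00173), and Slc51a, at 1479 and 409 (-1.86, adjusted p = 0.00202), fell. Proximal genes were not called by camera (median -0.196 but mean 0.104, adjusted p = 0.438, 3 higher and 1 lower, 3 and 2 adjusted over the list alone), and fry called them at 0.0059. Villus tip genes were not called (-0.816, adjusted p = 0.482, 2 higher and 3 lower, the same adjusted over the list alone).

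Fetal-like genes, which the intestinal epithelium turns on during repair, rose in DKO with a median of 3.33 and 12 of 14 members called, 0 lower (the same adjusted over the list alone, camera adjusted p = 4.46e-09, adjusted p = 0.286 with an estimated correlation). Anxa1 rose from 11.5 ± 1.08 to 473 ± 89.7 (5.23 ± 0.67, adjusted p = 0.000661). The growth factor gene Ereg rose from 31.6 ± 3.88 to 239 ± 53.8 (2.87 ± 0.23, adjusted p = 6.89e-05). The claudin gene Cldn4 rose from 157 ± 23.1 to 1142 ± 238 (2.84 ± 0.27, adjusted p = 0.000169) and Msln from 4.31 ± 0.169 to 29.9 ± 3.81 (2.53 ± 0.29, adjusted p = 0.000359). Ly6a rose from 37.9 ± 12.4 to 1112 ± 66.5 (4.88 ± 0.85, adjusted p = 0.00248), a call that DESeq2 did not make. Junction genes were not called (median 0.169, adjusted p = 0.0514, 8 higher and 2 lower, 9 and 2 adjusted over the list alone). They became called without WT replicate 1 (0.0158), WT replicate 3 (0.0416), AKO replicate 2 (0.0492), AKO replicate 3 (0.0499), DKO replicate 2 (0.0264) or DKO replicate 3 (0.00866), in each case lost with an estimated correlation (adjusted p from 0.572 to 0.712). Heat shock and immediate early genes rose (median 1.02, 7 higher, 0 lower, the same adjusted over the list alone, adjusted p = 0.000403, adjusted p = 0.286 with an estimated correlation). Egr1 went from 22.1 ± 7.75 to 131 ± 24.4 (2.56 ± 0.31, adjusted p = 0.000524). Dusp1 went from 8.38 ± 1.58 to 38.8 ± 8.05 (2.08, adjusted p = 0.000242).

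**Figure D3:**
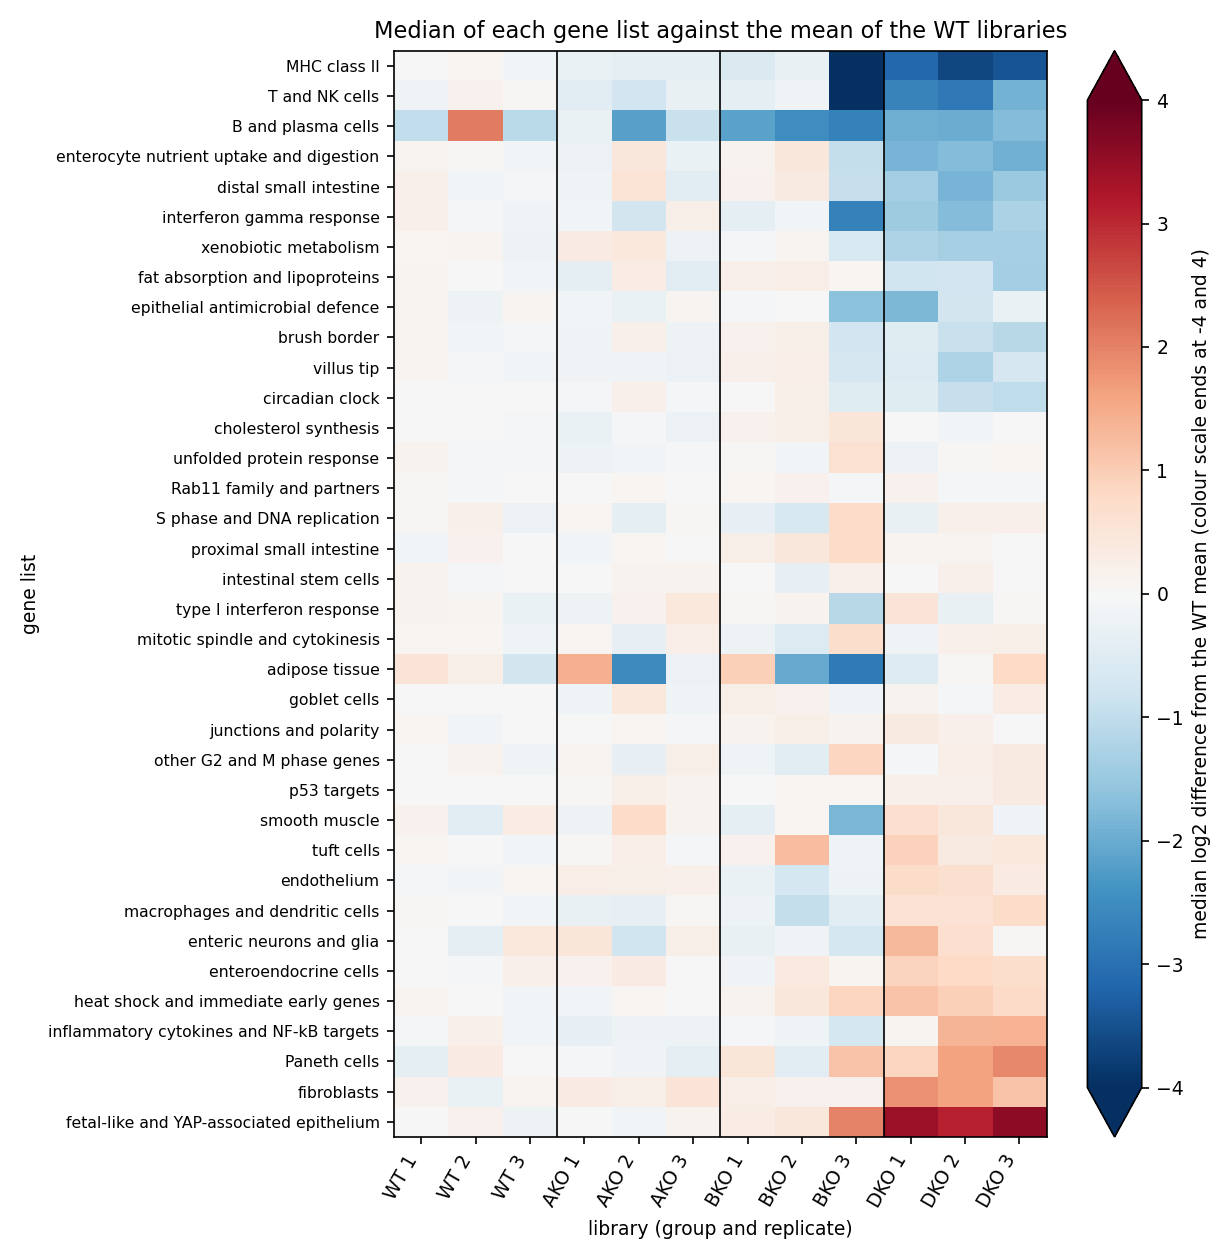
Median log2 difference from the WT mean over the members of each gene list, for each library; the colour scale ends at -4 and 4.

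Of the lists of secretory cells, those of Paneth, enteroendocrine and tuft cells were higher in DKO and that of goblet cells was not called. Paneth genes had a median of 1.46 with 10 higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 0.00127, adjusted p = 0.544 with an estimated correlation). Ang4 rose from 71.5 ± 33.3 to 340.0 ± 44.6 (2.34 ± 0.28, adjusted p = 0.000494). Defa23 went from 501 to 2401 (2.22 ± 0.38, adjusted p = 0.00215). By contrast, Defa21 fell from 534 to 6.35 (-6.79 ± 1.37, adjusted p = 0.0049). Defa2 went from 795 to 10 (-7.94, adjusted p = 0.00387). Reads of such near-identical gene copies cannot always be told apart. Enteroendocrine genes had a median of 0.629 with 9 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.000492, adjusted p = 0.286 with an estimated correlation). Cck went from 1.70 ± 0.218 to 10.8 ± 2.59 (2.11, adjusted p = 0.000275), and Tac1 from 9.10 to 40.9 ± 8.4 (2.05, adjusted p = 0.00101). Tuft cell genes had a median of 0.555 with 3 higher (5 adjusted over the list alone) and 0 lower (adjusted p = 0.00659, adjusted p = 0.544 with an estimated correlation), among them Ptgs1 (1.31, adjusted p = 0.00309). Goblet genes were not called (0.053, adjusted p = 0.314, 5 higher and 1 lower, the same adjusted over the list alone). Still, Spink4 rose from 364 ± 46.8 to 1064 ± 242 (1.53 ± 0.27, adjusted p = 0.00266). The entry named Clca1 rose from 3.68 ± 0.695 to 6.22 ± 0.925 (0.63 ± 0.17, adjusted p = 0.0164), a call lost without WT replicate 2 or DKO replicate 3 (up to 0.0622). By older symbols the goblet gene Clca1 is named Clca3 in the deposited values, so this entry, counted among the 5 higher, may be another gene. Antimicrobial genes were not called (-0.762, adjusted p = 0.2, 2 higher and 4 lower, the same adjusted over the list alone).

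No list of genes of dividing cells was called in DKO against WT. The spindle list of 50 had a median of 0.111 (adjusted p = 0.363, 1 higher and 1 lower, 0 adjusted over the list alone) and other G2 and M phase genes 0.17 (adjusted p = 0.177, 1 higher, 0 adjusted over the list alone). S phase genes had a median of 0.021 (adjusted p = 0.692, 0 called either way, 0 adjusted over the list alone). Mki67, chosen after its values were seen, was at 126 ± 18.3 in WT and 135 ± 15.4 in DKO (0.10, adjusted p = 0.802). The cytokinesis gene Anln rose (0.92, adjusted p = 0.0437), a call lost when any 1 library was left out except BKO replicate 2, BKO replicate 3 or DKO replicate 1 (up to 0.125), and without a filter on low values. Nusap1 fell (-0.74, adjusted p = 0.0253), a call lost without WT replicate 1, WT replicate 2, DKO replicate 1 or DKO replicate 2 (up to 0.089), and with scaling by total reads or the Xist state as a term. Cks1b rose from 14.3 to 31.9 (1.08, adjusted p = 0.0329), a call lost when any 1 WT or DKO library was left out (up to 0.111). Without DKO replicate 1 the spindle list (0.253) and the other G2 and M phase list (0.357) were called, at 0.0329 each, and lost with an estimated correlation (adjusted p = 0.761 each). The p53 targets rose (median 0.402, 0.179 without DKO replicate 3, 9 higher and 2 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.00837, adjusted p = 0.286 with an estimated correlation). Plk2 went from 4.81 ± 0.643 to 25.9 ± 3.36 (2.21, adjusted p = 0.000661). Phlda3 went from 2.37 ± 0.379 to 7.44 ± 0.62 (1.33, adjusted p = 0.000549). Stem cell genes were not called (0.048, adjusted p = 0.612, 3 higher and 3 lower, the same adjusted over the list alone). Prom1 rose from 91.5 to 174 (0.93, adjusted p = 0.00348), Axin2 fell from 75.7 to 40.3 (-0.88, adjusted p = 0.00725). Lgr5 and Olfm4 were chosen after their values were seen. Lgr5 was at 13.1 ± 3.28 and 11.9 ± 2.83 (adjusted p = 0.755), and Olfm4 at 253 ± 39.2 and 100.3 ± 40.9 (adjusted p = 0.0574).

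Lymphocyte and antigen-presentation genes were lower in DKO, while myeloid and inflammatory genes were higher. MHC class II genes had a median of -3.35 with 8 lower (9 adjusted over the list alone) and 0 higher (adjusted p = 0.00167, adjusted p = 0.544 with an estimated correlation). Ciita fell from 92.0 ± 11.2 to 3.44 ± 1.02 (-4.41, adjusted p = 0.0156), a call lost without DKO replicate 2 (0.0516). Interferon gamma genes had a median of -1.46 with 9 lower (14 adjusted over the list alone) and 0 higher (adjusted p = 0.00429, adjusted p = 0.661 with an estimated correlation). Gbp6 went from 48.9 to 4.73 (-3.04, adjusted p = 0.015), a call lost without WT replicate 1 or DKO replicate 2 (up to 0.0595). T and NK cell genes had a median of -2.56 with 5 lower (11 adjusted over the list alone) and 0 higher (adjusted p = 0.00167, adjusted p = 0.544 with an estimated correlation). Lck fell (-2.40, adjusted p = 0.0169), a call lost without WT replicate 2 or DKO replicate 2 (up to 0.0622). B and plasma cell genes had a median of -1.93 with 0 called members, 0 adjusted over the list alone (adjusted p = 0.0368, adjusted p = 0.544 with an estimated correlation). The list lost its call without WT replicate 2 (0.0714), BKO replicate 3 (0.0633), DKO replicate 1 (0.0627) or DKO replicate 3 (0.0612). Macrophage genes had a median of 0.646 with 6 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.00318, adjusted p = 0.544 with an estimated correlation). Cd163 went from 0.689 to 6.36 (2.16, adjusted p = 0.000999). Inflammatory genes had a median of 1.05 with 6 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.00481, adjusted p = 0.544 with an estimated correlation). Ptgs2 went from 1.92 ± 0.405 to 19.4 ± 2.55 (2.81 ± 0.21, adjusted p = 5.75e-05). The inflammatory list was at 0.533 without DKO replicate 1 and lost its call without DKO replicate 2 (0.234) or DKO replicate 3 (0.15). In these fits Cxcl1 and Il1a, at 1 or more only in the DKO libraries, were no longer tested, so the values do not show the part of 1 library alone. Type I interferon genes were not called (median 0.11 but mean -0.0093, adjusted p = 0.623, 5 higher and 4 lower, the same adjusted over the list alone). In BKO replicate 3 the MHC class II and T and NK cell lists lay at -5.61 and -4.03 from WT.

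Genes of fibroblasts, endothelium, neurons and glia, all outside the epithelium, were higher in DKO. Fibroblast genes had a median of 1.69 with 7 of 9 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.00032, adjusted p = 0.286 with an estimated correlation). Dcn went from 78.1 ± 7.99 to 257 ± 22.7 (1.71 ± 0.19, adjusted p = 0.000366). Col3a1 went from 97.9 ± 27.3 to 318 ± 88.7 (1.69, adjusted p = 0.00355). Endothelial genes had a median of 0.581 with 5 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.00167, adjusted p = 0.54 with an estimated correlation). Esam went from 3.19 to 10.2 ± 0.939 (1.42, adjusted p = 0.000359). Genes of neurons and glia had a median of 0.671 with 3 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.00837, adjusted p = 0.657 with an estimated correlation). Gfap went from 0.717 ± 0.51 to 10.8 ± 1.52 (2.82 ± 0.27, adjusted p = 0.00017). The list of neurons and glia lost its call without DKO replicate 1 (0.0684). Smooth muscle (0.306, adjusted p = 0.246, 1 higher, 0 adjusted over the list alone) and adipose genes (0.073, adjusted p = 0.777, 1 higher, 0 adjusted over the list alone) were not called. Of lists with fewer than 3 tested members, the list of neutrophils, eosinophils and mast cells had 2, Csf3r (0.86, adjusted p = 0.0109) and Mcpt1 (2.52, adjusted p = 0.032; lost when any 1 WT library, DKO replicate 1 or DKO replicate 2 was left out, up to 0.112, and with a pseudocount of 0.1), both higher. The pancreas list had 2, with Sycn lower (-0.89, adjusted p = 0.00657), red blood cells 2 with 0 called, and mitochondrially encoded genes 0.

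Lists of xenobiotic metabolism and circadian genes were lower in DKO. Xenobiotic metabolism had a median of -1.37 with 10 lower and 3 higher (the same adjusted over the list alone, adjusted p = 0.018, adjusted p = 0.54 with an estimated correlation). Of the carboxylesterase genes, Ces2a fell from 574 ± 134 to 11.5 ± 1.7 (-5.51, adjusted p = 0.000614) and Ces2e fell too (-1.99, adjusted p = 0.00101). Circadian genes had a median of -0.796 with 7 lower and 0 higher (8 and 1 adjusted over the list alone, adjusted p = 0.0183, adjusted p = 0.544 with an estimated correlation). Dbp went from 14.1 to 1.25 (-2.75 ± 0.49, adjusted p = 0.0028). The circadian list lost its call without DKO replicate 3 (0.0811). Cholesterol synthesis was not called (median -0.029, adjusted p = 0.453, 3 higher and 6 lower, the same adjusted over the list alone), though Dhcr7 fell from 79.5 ± 2.91 to 24.6 ± 3.39 (-1.66, adjusted p = 0.000383). Stard4 went from 286 ± 38.5 to 126 ± 6.16 (-1.16, adjusted p = 0.000242). The unfolded protein response was not called (median -0.039 but mean 0.211, adjusted p = 0.614, 5 higher and 3 lower, the same adjusted over the list alone). Ppp1r15a was higher (1.51, adjusted p = 0.000746) and Edem1 lower (-0.70, adjusted p = 0.00428). The Rab11 family with its partners was not called (median 0.050 but mean -0.151, adjusted p = 0.803, 3 higher and 5 lower, the same adjusted over the list alone). Quantile scaling and scaling by total reads turned the median of cholesterol synthesis (0.014 and 0.058) and of the unfolded protein response (0.087 and 0.049). In all, camera called 21 lists in DKO against WT (11 higher, 10 lower), 16 of them whichever library was left out, and fry 19.

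**Figure D4:**
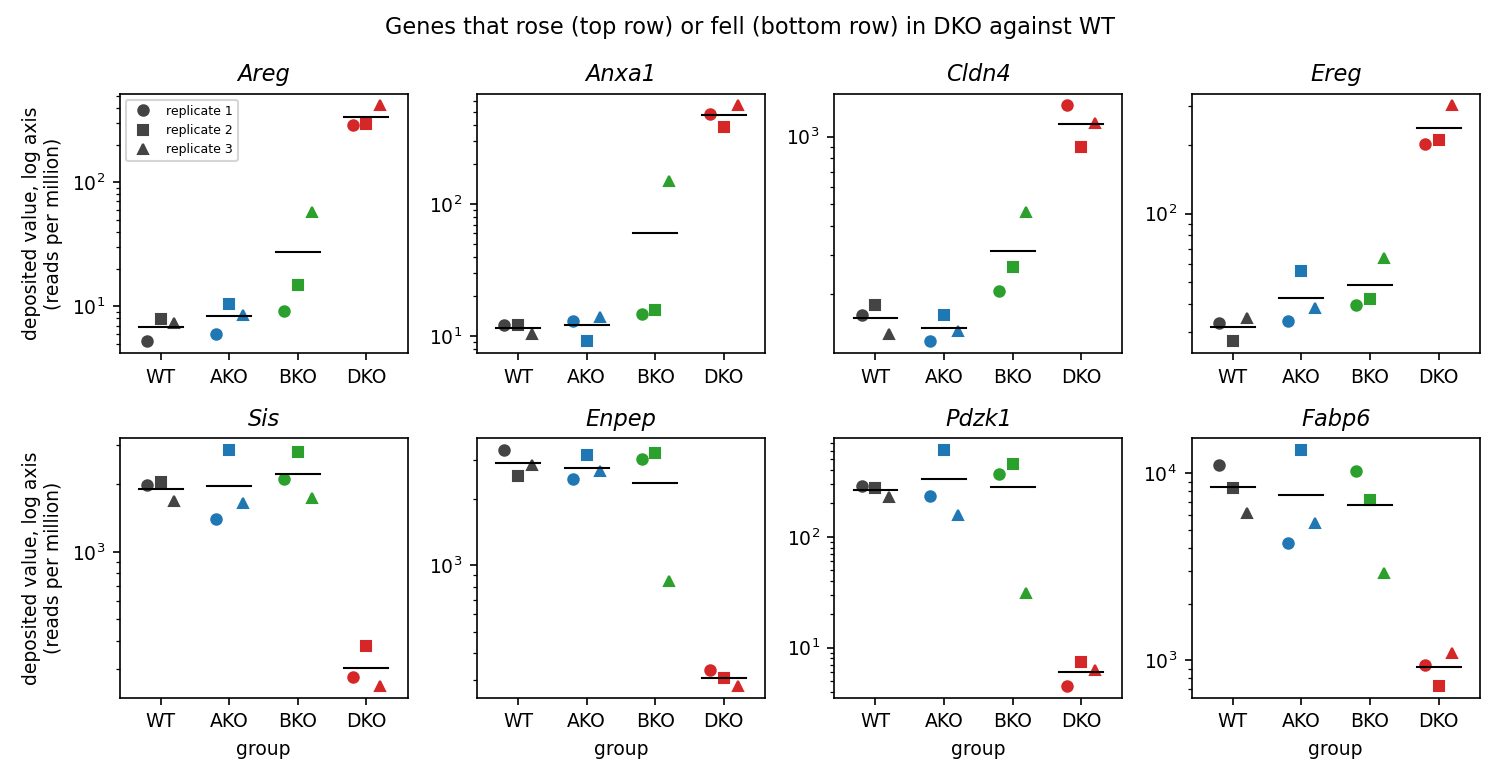
Values of Areg, Anxa1, Cldn4 and Ereg (top) and Sis, Enpep, Pdzk1 and Fabp6 (bottom) in each library on a log axis; the line is the mean of each group of 3.

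DKO against AKO compares groups without and with Rab11b that both carry the floxed Rab11a and Cre, though Rab11a itself was also higher in DKO. It called 4410 genes (2087 higher, 2323 lower; 6004 at an unadjusted p under 0.05), 1857 at least 2-fold (941 higher, 916 lower), with 4283 in edgeR and 5139 in DESeq2. Areg rose from 8.29 ± 2.23 in AKO (log2 change 5.17 ± 0.51, adjusted p = 0.000189, n = 3 per group), as did Cldn4 from 141 ± 19.7 (3.0 ± 0.27, adjusted p = 0.000139) and Anxa1 from 12 ± 2.57 (5.19 ± 0.67, adjusted p = 0.000715). Sis fell from 1972 ± 775 (-2.66 ± 0.28, adjusted p = 0.000265), Ppara from 76.0 ± 16 (-3.34 ± 0.39, adjusted p = 0.000404), Ces2a from 540.2 ± 174 (-5.39 ± 0.69, adjusted p = 0.00068) and Cyp2c55 from 253 ± 162 (-7.39 ± 1.00, adjusted p = 0.000879). Enterocyte genes had a median of -1.76 with 18 lower (the same adjusted over the list alone, adjusted p = 3.59e-09, adjusted p = 0.518 with an estimated correlation). Fetal-like genes had 3.39 with 12 higher (adjusted p = 3.59e-09, adjusted p = 0.365 with an estimated correlation). Paneth genes had 1.64 with 11 higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 0.000486, adjusted p = 0.644 with an estimated correlation). Ang4 was higher (2.5 ± 0.28, adjusted p = 0.00036). Macrophage genes had 0.851 with 8 higher (10 adjusted over the list alone, adjusted p = 0.000743, adjusted p = 0.518 with an estimated correlation). Fibroblast genes had 1.1 with 5 higher (6 adjusted over the list alone, adjusted p = 0.00805, adjusted p = 0.518 with an estimated correlation). Dcn was higher (1.72 ± 0.19, adjusted p = 0.00036). Camera called 19 lists (10 higher, 9 lower), fry 15, and 0 were called with an estimated correlation (lowest adjusted p = 0.365). Lost were tuft cells without DKO replicate 1 (0.0522), fat uptake without AKO replicate 2 (0.086) or DKO replicate 3 (0.056), brush border without DKO replicate 3 (0.0826), and circadian genes without DKO replicate 3 (0.0536). Also lost were neurons and glia without AKO replicate 2 (0.0868) or DKO replicate 1 (0.0855), and endothelium without AKO replicate 3 (0.0826), BKO replicate 3 (0.0821), DKO replicate 1 (0.12) or DKO replicate 2 (0.0579). With an estimated correlation the adjusted p of these lists was 0.687 for tuft cells, 0.677 for fat uptake, 0.73 for brush border, 0.677 for circadian genes, 0.717 for neurons and glia and 0.687 for endothelium. The gene count was 2782 without DKO replicate 2.

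DKO against BKO compares groups that both have the Rab11b null genotype, in which some Rab11b transcript remained, with and without deletion of floxed Rab11a. It called 3144 genes (1498 higher, 1646 lower, with 5136 at an unadjusted p under 0.05), 1372 at least 2-fold (845 higher, 527 lower). EdgeR called 3025 and DESeq2 4097. The limma p-values use a spread shared by all 4 groups, so they can understate the spread of the BKO libraries, of which replicate 3 lay apart. With only DKO and BKO in the fit, 753 genes were called. Retnlb rose from 0.729 ± 0.577 in BKO (log2 change 4.03 ± 0.30, adjusted p = 0.000163, n = 3 per group) and Areg from 27.3 ± 26.5 (3.95 ± 0.51, adjusted p = 0.000987). Il33 went from 5.67 ± 1.02 to 17.2 ± 1.12 (1.46 ± 0.19, adjusted p = 0.00098). Sis fell from 2217 ± 546 (-2.87 ± 0.28, adjusted p = 0.0003). Mttp, needed to load fat onto lipoproteins, went from 1145 ± 395 to 345 ± 46.4 (-1.68 ± 0.23, adjusted p = 0.00123). Enterocyte genes had a median of -1.76 with 19 lower (the same adjusted over the list alone, adjusted p = 1.53e-10, adjusted p = 0.298 with an estimated correlation). Fat uptake genes had -1.48 with 12 lower and 2 higher (13 and 3 adjusted over the list alone, adjusted p = 4.13e-05, adjusted p = 0.249 with an estimated correlation). Fetal-like genes had 2.11 with 11 higher (13 adjusted over the list alone, adjusted p = 7.55e-09, adjusted p = 0.249 with an estimated correlation). Cholesterol synthesis was lower here (-0.35, or -0.22 without BKO replicate 3, 9 lower, 10 adjusted over the list alone, adjusted p = 0.000148, adjusted p = 0.259 with an estimated correlation), with Dhcr7 down from 78.0 ± 20.6 (-1.60 ± 0.19, adjusted p = 0.000808). Sqle went from 430.4 ± 30.2 to 289 ± 25.8 (-0.57 ± 0.11, adjusted p = 0.00529), though Sqle was not called with only these groups in the fit. Macrophage genes had 1.37 with 10 higher (12 adjusted over the list alone, adjusted p = 8.65e-07, adjusted p = 0.249 with an estimated correlation). Endothelial genes had 1.04 with 10 higher (11 adjusted over the list alone, adjusted p = 2.04e-06, adjusted p = 0.249 with an estimated correlation). Inflammatory genes had 1.25 (0.625 without DKO replicate 2, when Cxcl1 and Il1a were no longer tested) with 7 higher (9 adjusted over the list alone, adjusted p = 1.02e-05, adjusted p = 0.261 with an estimated correlation). C1qb rose from 14.6 ± 4.82 to 45.8 ± 2.81 (1.64 ± 0.23, adjusted p = 0.00138) and Plvap from 10.4 ± 2.41 to 26.9 ± 5.26 (1.29 ± 0.18, adjusted p = 0.00138).

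In the same comparison, immune and cell-cycle lists depended on BKO replicate 3, in which T-cell and MHC class II genes lay far below WT, as in DKO. MHC class II genes (-1.09), T and NK cells (-1.03) and interferon gamma genes (-0.341) were not called, and without BKO replicate 3 they were called lower at -2.94 (adjusted p = 3.07e-05), -2.45 (adjusted p = 3.07e-05) and -1.19 (adjusted p = 0.00028). These calls were lost with an estimated correlation (adjusted p = 0.446, 0.446 and 0.527). Spindle (0.166), other G2 and M phase (0.246) and S phase genes (0.104) were not called. Without BKO replicate 3 they were called higher at 0.525 (adjusted p = 0.000162), 0.514 (adjusted p = 0.00231) and 0.565 (adjusted p = 0.000206), calls that were lost with an estimated correlation (adjusted p = 0.572 for each). Without DKO replicate 1 spindle (0.291, adjusted p = 0.0135) and S phase genes (0.311, adjusted p = 0.0172) were called, and lost with an estimated correlation (adjusted p = 0.819 each). Camera called 19 lists (12 higher, 7 lower), fry 15, and 0 were called with an estimated correlation (lowest adjusted p = 0.249). Lost were p53 targets without BKO replicate 3 (0.0519), brush border without DKO replicate 3 (0.0505), smooth muscle without BKO replicate 3 (0.163), and type I interferon without DKO replicate 1 (0.213) or BKO replicate 3 (0.941). With an estimated correlation the adjusted p was 0.249 for p53 targets, 0.714 for brush border, 0.692 for smooth muscle and 0.873 for type I interferon. The gene count was 1631 without BKO replicate 1, 1960 without BKO replicate 2, 6224 without BKO replicate 3 and 1797 without DKO replicate 2. Scaled by the total reads of each library, 2073 genes were higher and 967 lower (68.2% higher, against 47.6%), and the median of all genes was 0.151 (0.0013 as deposited). With only the groups compared in the fit, 753 genes were called (461 higher, 292 lower), and with quality weights 6134.

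The interaction asks where the DKO change was more or less than the sum of both single changes. It was called for 541 genes (284 higher, 257 lower; 3263 at an unadjusted p under 0.05), 427 of at least 2-fold (251 higher, 176 lower), with 352 in edgeR and 1783 in DESeq2. Retnlb (interaction 4.13 ± 0.43, adjusted p = 0.00454), Cwh43 (4.0 ± 0.61, adjusted p = 0.0129), the imprinted RNA H19 (3.61 ± 0.50, adjusted p = 0.00863), Dusp1 (2.51 ± 0.30, adjusted p = 0.0063), Gfap (2.24 ± 0.38, adjusted p = 0.018) and Cxcl1 (1.75 ± 0.29, adjusted p = 0.016) exceeded the sum. Sis fell below it (-2.85 ± 0.39, adjusted p = 0.00863, n = 3 per group). These kept their call in every leave-out in which they were tested, but Cxcl1, at 1 or more only in the DKO libraries, was not tested without DKO replicate 1, DKO replicate 2 or DKO replicate 3. In contrast, edgeR and DESeq2 did not call Retnlb or Cxcl1, and Gfap was not called by edgeR or with a pseudocount of 0.1. H19 was at 0.298 in WT, 0.306 in AKO, 0.65 in BKO and 20.9 ± 13.3 in DKO. Ppara (-3.21 ± 0.55, adjusted p = 0.0178) lost its call without WT replicate 3, AKO replicate 1 or DKO replicate 2 (up to 0.0529). Ereg (1.90 ± 0.33, adjusted p = 0.0189) lost it without WT replicate 1, WT replicate 3 or AKO replicate 1 (up to 0.0541). Enterocyte genes had a median of -1.76 with 4 lower (18 adjusted over the list alone, adjusted p = 8.36e-11, adjusted p = 0.395 with an estimated correlation). Fetal-like genes had 2.31 with 5 higher (12 adjusted over the list alone, adjusted p = 8.49e-09, adjusted p = 0.395 with an estimated correlation). Macrophage genes had 1.57 with 4 higher (12 adjusted over the list alone, adjusted p = 1.4e-07, adjusted p = 0.395 with an estimated correlation). Inflammatory genes had 1.51 with 4 higher (10 adjusted over the list alone, adjusted p = 4.17e-07, adjusted p = 0.395 with an estimated correlation). Spindle (0.171, adjusted p = 0.573), other G2 and M phase (0.156, adjusted p = 0.499) and S phase genes (0.193, adjusted p = 0.282) were not called, though spindle genes were without BKO replicate 3 (0.543, adjusted p = 0.00129), a call lost with an estimated correlation (adjusted p = 0.678). Camera called 17 lists (11 higher, 6 lower), fry 8, and 0 were called with an estimated correlation. Among the former, enteroendocrine genes lost their call without AKO replicate 3 (0.0649), BKO replicate 1 (0.0522) or BKO replicate 3 (0.0506), and brush border without DKO replicate 3 (0.103). Smooth muscle genes (0.685, adjusted p = 0.0307, adjusted p = 0.894 with an estimated correlation) lost it without WT replicate 1 (0.0628), WT replicate 3 (0.0872), AKO replicate 1 (0.127), AKO replicate 3 (0.0545), BKO replicate 3 (0.567), DKO replicate 1 (0.0787) or DKO replicate 2 (0.053), and their median was 1.06 without AKO replicate 2 and 1.16 without BKO replicate 2. B and plasma cell genes (1.75, adjusted p = 0.0403, adjusted p = 0.559 with an estimated correlation) lost it without WT replicate 2 (0.0585), AKO replicate 2 (0.141), BKO replicate 3 (0.236) or DKO replicate 3 (0.0602). The gene count was 94, 157 and 111 without WT replicates 1, 2 and 3, 101, 170 and 239 without AKO replicates 1, 2 and 3, 168, 228 and 4181 without BKO replicates 1, 2 and 3, and 236, 112 and 212 without DKO replicates 1, 2 and 3. Scaled by the total reads of each library, 367 genes were higher and 179 lower (67.2% higher, against 52.5%), and the median of all genes was 0.138 (0.025 as deposited). The balance went the other way in edgeR (138 higher, 214 lower), in DESeq2 (671 and 1112) and with the Xist state as a term (676 and 1025).

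Across comparisons, 1 gene changed in AKO and in DKO against WT (Rab11a, lower in both). In BKO and DKO 5 did: Kcnk6 higher, and Rab11b, H2-Bl, Gdpd3 and Gm8801 lower. Independent lists would share 0.146 higher and 0.86 lower, a figure that leaves out the shared WT libraries. Of the 5, Rab11b was itself targeted in both groups, and H2-Bl and Gm8801 lie within 10 megabases of it. In 100 simulations of unchanged groups with the WT libraries shared, BKO and DKO shared 0 calls on average. Unchanged groups have few calls to share, so this figure cannot say whether the overlap exceeds chance. AKO and BKO shared 0. Of the genes called in DKO against WT, 3733 were also called in the same direction against AKO, 2501 against BKO, 2351 against both, and 505 in the interaction. Because the comparisons share the WT libraries, log2 changes of all genes would correlate without any effect. Across genes, which are not independent replicates, BKO and DKO correlated at 0.576 (0.502 in 100 simulations without change), AKO and DKO at 0.188 (0.502), and AKO and BKO at 0.355 (0.501). The covariance was 0.221 for BKO and DKO (0.0439 without change), 0.038 for AKO and DKO (0.0438) and 0.0351 for AKO and BKO (0.0437). Without BKO replicate 3 the correlation of BKO and DKO was 0.138 and the covariance 0.0444. With 3 WT libraries the controls could not be split into parts of 2, so the part of any excess that comes from shared controls was not separated.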

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

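The tests on BKO replicate 3, and on the share of epithelium and the Xist state behind the enterocyte change, were chosen only after those results were seen. The splits of the samples and the test on the neighbours of Rab11b were set beforehand. For the neighbours, the rule for the verdict was written only after the result was seen.

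The interaction stood out because the effect of losing Rab11a differed with the state of Rab11b for 541 genes by the test of the interaction itself. Retnlb (log2 4.13), Cwh43 (4.0), Areg (3.72), H19 (3.61) and Ly6c1 (3.53) exceeded the sum of both single changes, and Akr1c14 (-4.41), Slc1a1 (-3.87), Cubn (-3.49), Edn2 (-3.42) and Acaa1b (-3.33) lay below it. Retnlb, Cwh43 and H19 kept their call whichever library was left out. Edn2 lost it when any 1 of these was left out: a WT library, AKO replicate 1, AKO replicate 2, DKO replicate 2 or DKO replicate 3 (adjusted p up to 0.0612), and Acaa1b without WT replicate 1, WT replicate 3, AKO replicate 1 or DKO replicate 2 (0.0541). Areg lost it when any 1 of these was left out: a WT library, AKO replicate 1, AKO replicate 3, BKO replicate 2, DKO replicate 2 or DKO replicate 3 (0.0685), and Ly6c1 when any 1 of these was: a WT or AKO library, BKO replicate 1, DKO replicate 2 or DKO replicate 3 (0.0678). Akr1c14 (0.0942), Slc1a1 (0.0921) and Cubn (0.0989) lost it when any 1 library was left out except BKO replicate 3. Of 100 relabelings of the samples, the real one included, 6 gave at least 541 genes, the highest other giving 3801. The 5 others all put 3 of the 4 libraries BKO replicate 3, DKO replicate 1, DKO replicate 2 and DKO replicate 3 in 1 group. So did 8 of the 99 other relabelings. Relabeling all 12 libraries lets the large difference of these libraries from the rest appear as an interaction. The relabelings therefore cannot decide on chance for this count, and chance was not excluded.

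With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real splits called 1 gene in AKO against WT (highest other 1, so 2 of the 10 gave as many), 6 in BKO against WT (highest other 0), 4348 in DKO against WT (1), 4410 in DKO against AKO (2) and 3144 in DKO against BKO (2057), with only the real split, 1 of 10, reaching its count in each of the last 4. The split behind 2057 set BKO replicate 1, BKO replicate 2 and DKO replicate 1 against BKO replicate 3, DKO replicate 2 and DKO replicate 3.

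BKO replicate 3 lay near the DKO libraries and away from the other BKO libraries. A DKO sample under a BKO label is excluded by Rab11a, at 275 in that library against 96 to 111.5 in the DKO libraries. A higher share of epithelium with an unchanged mix of cell types is excluded as the whole cause, since it would raise epithelial genes alike. The junction list minus the enterocyte list lay 1.23 log2 above the other BKO libraries (0.155 against -0.968 in BKO replicate 3). The range of that difference over the WT, AKO and other BKO libraries was 0.617. This test replaced that on fibroblasts against T and NK cells (3.73, the same verdict). A higher share as a part of the cause was not excluded. Nor was a higher share with another mix of epithelial cells. In BKO replicate 3 the S phase and Paneth lists lay at 0.747 and 1.13 from WT, and the goblet list at -0.145. A piece from another stretch of the intestine stays open: 70% of the distal genes lay below every other WT, AKO and BKO library, but of the proximal genes 28.6% lay above and 28.6% below. Infection or injury may also be a cause, and the labels hold nothing to test it.

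Of the 6 genes called in BKO against WT, Gm8801 and H2-Bl lie near Rab11b. Within 10 megabases of Rab11b in GRCm38, 2 of 340 tested genes (0.588%) were called, against 3 of 13278 elsewhere (0.0226%), an odds ratio of 26.2 (two-sided Fisher's exact test, p = 0.00591, adjusted p = 0.0355 over 6 such tests). In DKO against WT the shares were 37.4% and 31.7% (adjusted p = 0.0622) and in DKO against AKO 32.9% and 32.2% (adjusted p = 0.977), where the many other calls leave little room for 2 genes to show. The test itself was set beforehand, but the rule for its verdict was written after these 2 genes had been seen near Rab11b. The verdict, at first a fit, was therefore changed to undecided. Strain sequence carried along with the allele may be a cause but cannot be told apart from a direct effect of Rab11b loss. H2-Bl also has near-identical copies whose reads cannot always be separated.

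Enterocyte genes were lower in DKO by a list median of -1.88. A lower share of epithelium in the piece, with an unchanged mix of cell types, is excluded as the whole cause. The junction list, also epithelial, lay 2.02 log2 above the enterocyte list in the DKO libraries (0.185 against -1.84, with ranges summing to 0.565). That test too replaced one on fibroblasts against T and NK cells (3.99, the same verdict), since T-cell markers include lymphocytes within the epithelium. The Xist state of the animals, high in all 3 DKO libraries, is excluded too as the whole cause. The lowest Xist-high library of the other groups lay at 0.111, against -1.73 for the highest DKO library. With the Xist state as a term the median was -2.37, though that term drew in part on BKO replicate 3, the Xist-low library of its group. No DKO library was Xist-low, so a DKO change limited to Xist-high animals was not excluded. A shift among epithelial cell types and another stretch of intestine (distal -1.58, proximal -0.20) stay open, so loss of enterocyte maturation may be a candidate but was not told apart from them.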

How the results depend on the processing

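Total-read scaling, Xist state as a term, BKO replicate 3 and WT replicate 2 both left out, older symbols and the estimated correlation with each library left out were tests chosen only after the results were seen.

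Over the settings tried, 345 gene counts stayed within 1.5 times, 138 moved and 3 counts of higher genes in AKO against WT left 0. List tests kept their camera direction and call state in 4156 cases, while 1449 lost and 110 gained a call. The camera direction turned without a call in 309 cases and with a call in 24. Most of the lost list calls came from the settings with an estimated correlation. Named genes stayed in 13042 cases, 751 lost and 249 gained a call, 26 moved and 0 turned. Sample quality weights gave 4 genes in AKO against WT, 50 in BKO against WT, 9655 in DKO against WT, 9368 in DKO against AKO, 6134 in DKO against BKO and 4752 in the interaction; the cause was not tested. DESeq2 gave 3 in AKO against WT, 249 in BKO against WT and 1783 in the interaction, for which edgeR gave 352, and the cause was not tested. In the self-test DESeq2 called 13 unchanged genes in BKO against WT and 31 in the interaction, far fewer than these counts. The self-test held no outlying library like BKO replicate 3, so its rates may not carry over. Without a filter 2 genes were called in AKO against WT, and with the stricter filter 3 in BKO against WT, with other numbers of genes tested. Only the groups compared in the fit gave 2 in BKO against WT and 753 in DKO against BKO. The same setting gave more calls than the main fit in DKO against WT (5533) and DKO against AKO (5224), and the cause was not tested. The Xist term gave 1701 in the interaction; the cause was not tested. With BKO replicate 3 and WT replicate 2 both left out DKO against BKO gave 6193 and the interaction 3428, and in BKO against WT the list medians were -0.21 for other G2 and M phase, 0.316 for enterocytes, 0.153 for brush border, 0.15 for type I interferon and -0.095 for the unfolded protein response; type I interferon in DKO against BKO was 0.086. With the estimated correlation and BKO replicate 3 left out, type I interferon was 0.11 and the unfolded protein response -0.051 in BKO against WT, and type I interferon 0.086 in DKO against BKO.

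Leaving out 1 library each time, the counts ran from 3 (without WT replicate 1, among others) to 9 (without BKO replicate 1) in BKO against WT, 2691 (DKO replicate 2) to 6153 (BKO replicate 3) in DKO against WT, 2782 (DKO replicate 2) to 6203 (BKO replicate 3) in DKO against AKO, 1631 (BKO replicate 1) to 6224 (BKO replicate 3) in DKO against BKO, and 94 (WT replicate 1) to 4181 (BKO replicate 3) in the interaction. List medians in BKO against WT ran from a value without BKO replicate 3 to one without BKO replicate 2 for spindle (-0.39 to 0.219), other G2 and M phase (-0.28 to 0.328), S phase (-0.50 to 0.201) and the unfolded protein response (-0.051 to 0.24), and from BKO replicate 2 to BKO replicate 3 left out for enterocytes (-0.37 to 0.301), distal genes (-0.43 to 0.237), tuft cells (-0.068 to 0.658) and type I interferon (-0.68 to 0.11); brush border ran from -0.24 (BKO replicate 1) to 0.222 (BKO replicate 3). In AKO against WT enterocytes ran from -0.19 (AKO replicate 2) to 0.093 (AKO replicate 3), interferon gamma from -0.38 (AKO replicate 3) to 0.082 (AKO replicate 2) and smooth muscle from -0.040 (AKO replicate 2) to 0.429 (AKO replicate 1). In DKO against BKO type I interferon ran from 0.086 (BKO replicate 3) to 0.832 (DKO replicate 2).

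The labels do not pair the samples: of 18 pairs with the same number, 4 correlated above 0.1 (-0.299 to 0.184). As a check, the replicate number as a block gave 3 genes in BKO against WT and 329 in the interaction; the cause was not tested.

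The depth of 19.2 M to 29.8 M recovered reads set 1 read at 0.0313 to 0.0563, so means well under 1 rest on few reads.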

Other observations

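The tests on symbol families and on genes present or absent by library were chosen only after the results were seen, while the test on suckling-type genes was set beforehand.

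Grouped by the stem of the gene symbol, 219 families were tested for an excess of called genes in DKO against WT (438 one-sided Fisher's exact tests, 18 called, the same direction under every scaling). The test treats genes of a family as independent, though they can change together, so its p does not measure the spread between libraries. No test with an estimated correlation was run on the families. Higher were 18 of 27 collagens (Col, adjusted p = 2.28e-07), 11 of 16 matrix metalloproteinases (Mmp, 0.000117), 8 of 11 annexins (Anxa, 0.00138), 9 of 15 defensins (Defa, 0.00285, with 3 lower, in copies whose reads cannot always be told apart) and 9 of 15 keratins (Krt, 0.00285), and also Fkbp, Dusp and Pla families, against 14.5% to 14.6% of other genes. Lower were 93 of 269 solute carriers (Slc, 1.33e-09, with 42 higher), 14 of 18 aldehyde dehydrogenases (Aldh, 4.31e-06, with 4 higher), 89 of 307 zinc finger genes (Zfp, 1.82e-05, with 12 higher), 18 of 34 cytochromes P450 (Cyp, 0.00016, with 3 higher) and 10 of 16 peroxisome genes (Pex, 0.00285), and also Rdh, Ces, Hsd, Gimap and Apol families, against 16.9% to 17.2% of other genes. Krt7 went from 127 ± 17.4 to 1111 ± 166 (3.11 ± 0.42, adjusted p = 0.000872), Krt23 from 7.44 ± 0.476 to 105.3 ± 9.07 (3.65 ± 0.48, adjusted p = 0.000737), Mmp10 from 5.83 ± 3.03 to 53.5 ± 9.96 (3.08 ± 0.48, adjusted p = 0.00154) and Col4a1 from 45.1 ± 4.71 to 187 ± 67.6 (1.96 ± 0.24, adjusted p = 0.000601). Aldh1b1 fell from 971 ± 43.3 to 208 ± 27.4 (-2.23 ± 0.20, adjusted p = 0.00011), while Aldh1a3 rose from 8.48 to 56.9 (2.63, adjusted p = 0.000252) and Rdh10, of the same retinoid pathway, from 14.2 to 73.0 (2.28, adjusted p = 0.000288). These genes were chosen after their values were seen.

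Although the tissue is given as jejunum, genes of the ileum were abundant in WT (Fabp6 at 8483 ± 2457, Slc10a2, chosen after its values were seen, at 651 ± 54.2).

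Present at 20 or more in some libraries and at 1 or less in all others were 15 genes, thresholds and genes being chosen after their values were seen, and all 15 split within at least 1 group. Kctd12 was listed at 0 in AKO replicate 2 and all DKO libraries and at 81.8 to 116.5 elsewhere. Zbed5 was at 0.263 in AKO replicate 3 and at 66.1 to 103.1 elsewhere, and Eif3j2 was listed at 0 in BKO replicate 2. Cyp3a25 was listed at 0 in DKO and at 100.1 in WT. The cause was not tested. Xist, Ddx3y and Eif2s3y were among the 15. Xist was high in WT replicate 1, AKO replicate 2, BKO replicate 1, BKO replicate 2 and all DKO libraries. Ddx3y and Eif2s3y, genes of the Y chromosome, were at 0.117 or less in those libraries and at 36.9 or more in all others. The Xist state therefore marks the sex of the animals, with the pattern of females where Xist was high.

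A return to suckling-type enterocyte expression was tested as a hypothesis for DKO. Of 7 genes 6 were tested, with a median of 0.44 (camera p = 0.297, and 0.361 with an estimated correlation). Dab2 rose from 4.51 to 21.7 (2.07) and Lrp2 from 0.112 to 1.41 (1.09), while Fcgrt fell from 97.8 to 38.4 (-1.33). A p of 0.05 or more had been set to exclude it, which was wrong, since a p that misses a threshold does not show absence and 6 genes going both ways decide little, so a partial return may still hold.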
